A study of Homo sapiens with 9 samples.

How the data were processed

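The data are whole-transcriptome microarray measurements of LNCaP cells, an established line from human prostate cancer that grows in response to androgen. Each of 9 groups had 1 array of the Affymetrix U133 Plus 2.0 type with 54675 probe sets. The deposited values are log2 expression values, and RMA is the tool named per the submitters' processing notes; its version and any later step are not given in the sources used here. RMA corrects background, makes the distributions of the arrays alike by quantile normalization and sums the probes of each probe set, so a change shared by most genes would be removed before the values were written. The array medians lay between 5.61 and 5.72 on the log2 scale, and no value was missing.

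Probe sets were named from the annotation of the platform. Of all probe sets, 41097 had exactly 1 gene symbol, 1801 had several and 11777 had none, and 62 of them were the manufacturer's control probe sets. Of those with 1 symbol, 41043 matched a RefSeq record by gene ID (assembly GRCh38.p14, used for names and gene span only) and 0 symbols needed an update. Some genes are not reported here. Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 19775 genes, of which 10523 had more than 1 probe set. Genes whose mean lay below the 40th percentile were left out of the tests, which left 11865. Gene names follow the annotation, and close paralogs such as the UGT2B and histone genes can share probes, so their values are uncertain as to the member measured. Histone values are also not read as a measure of DNA replication, since they were lower in steady state while replication genes were higher.

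RNA quality was read from the control probe sets for the 3' and 5' ends of the beta-actin transcript. The 3' minus 5' difference was between 0.38 and 0.70 (log2) on the inhibitor-series arrays and between 2.38 and 3.09 on the shRNA-series arrays. For the GAPDH control probe sets it was between 0.17 and 0.25 and between 0.52 and 0.64. Whether RNA quality or the handling of the sorted cells gave this difference between the series was not tested. Pearson correlations over probe sets lay between 0.950 and 0.995 within a series and between 0.880 and 0.916 between the series. At most 6.39% of probe sets had exactly equal values on any 2 arrays of a series, so no array was a copy of another.

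Tests were made in R 4.3.3 with limma 3.58.1 on the deposited log2 values, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 array per group, the only replication is that DHT was set against vehicle in 3 backgrounds: the inhibitor series, sh-control cells and sh-TOP2B cells. An additive limma fit held the 3 backgrounds as blocks, a DHT term and 1 term each for the steady-state, etoposide and merbarone arrays. It left 2 residual degrees of freedom per gene, to which the empirical Bayes step (with a trend on mean level) added 4.62 prior degrees of freedom. The spread is therefore how far the 3 DHT effects differ, and it includes real differences between the backgrounds. Lone arrays were compared directly with their reference array, under the assumption that they vary like the arrays of the 3 pairs. Genes whose DHT response differs between backgrounds therefore have a larger spread in these comparisons too. Nothing in the labels says that arrays came from separate cultures beyond their groups, so p-values measure only the spread between these samples. A fit with a term for DHT in sh-TOP2B cells, used for the difference between DHT responses, left 1 residual degree of freedom and had 5.16 prior degrees of freedom. Its spread is how far the DHT effects of the inhibitor series and sh-control cells differ. Counts of genes with a log2 difference of at least 1 are given beside the tests.

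Before the data were examined, 20 gene lists and the rule for naming genes were fixed. For each comparison the rule took the 5 genes with the largest rise and the 5 with the largest fall past the test, then the 3 leading members of each list whose camera call passed, and in every comparison 8 genes of topoisomerase II and the androgen response, of which 6 are named by a probe set used here. Where fewer than 5 genes passed, the largest differences of at least 1 were named with values only. Genes outside the rule are said to have been chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals of the additive fit, with adjustment over the lists of a comparison. Estimates below 0 were set to 0. The estimate was 0 for the histone, heat shock, luminal identity, break repair, topoisomerase and neuroendocrine lists, so for these the second test is no stricter and no further support. It was 0.63 for androgen-induced, 0.73 for androgen-repressed, 0.60 for replication and 0.61 for unfolded protein response genes. The residuals hold differences between the DHT effects of the pairs. The steady-state, etoposide and merbarone arrays have their own terms and add nothing to them. For comparisons of these arrays the estimate is therefore borrowed from the pairs, and a list that fails with it may still have shifted. List medians were set against 10000 random lists of the same size matched on mean expression. Genes that respond to DHT were chosen in one series and measured in the other, so that no array served both ends. A later check on bright probe sets is an exception.

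The fit was tested on simulated data for 11865 genes, of which 100 were changed by log2 1 and 100 by log2 2. For the DHT effect it recovered 85% of the smaller and 100% of the larger changes, and for the knockdown effect 65% and 98%. For etoposide against DHT it recovered 36% and 86%, and for the difference between DHT responses 4% and 25%. The simulated DHT and knockdown effects were the same in every pair, while the real DHT effects differed in size between pairs. These shares may therefore not hold for the data. The number of arrays limits the precision.

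The alternatives were no filter and a stricter filter (60th percentile) on dim genes, the median over probe sets, no intensity trend, robust prior variances, quantile normalization again, centring on control genes, a constant of 16 added on the linear scale, each pair left out in turn, and fits on subsets of arrays. A comparison of the lone arrays with the level fitted from all 3 pairs, a shift by the median difference of control genes, and lists without members below the array median on all arrays compared were chosen after seeing the data, as was the rule that a level below the array median gives a bound only. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.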

Results

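Gene expression was measured in LNCaP prostate cancer cells under androgen deprivation, after stimulation with the androgen dihydrotestosterone (DHT), and with topoisomerase II inhibited or TOP2B lowered. TOP2B encodes topoisomerase II beta, an enzyme that passes DNA strands through each other. In the inhibitor series, 1 array each came from cells grown in 10% serum (steady state), cells deprived of androgen for 48 h in 5% charcoal-stripped serum (vehicle), deprived cells given 100 nM DHT for 16 h, and deprived cells given 100 µM etoposide or 100 µM merbarone 2 h before DHT. Etoposide traps topoisomerase II on cut DNA, and merbarone blocks its catalytic cycle. In the shRNA series, cells were transfected with an sh-control or an sh-TOP2B vector that also made green fluorescent protein, deprived of androgen, given vehicle or DHT, and sorted for fluorescence, with 1 array each. Values are log2 RMA values, and differences are log2 differences with the limma standard error (SE). A level below the median of its array (5.61 to 5.72) is called dim. A difference that rests on a dim level is given as a bound ("at least"), with that level raised to the median, and a gene dim on all arrays compared is given no difference. A p-value beside a bound was computed from the deposited difference, not from the bound.

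Among genes past the test, DHT raised those of 2 prostate kallikreins by more than 5. KLK2, which encodes a secreted prostate protease, was dim in all 3 vehicle arrays (4.04, 5.50 and 5.64) and rose by at least 5.38 (limma adjusted p = 0.00225). KLK3, which encodes prostate-specific antigen, rose by 5.10 ± 0.11 (SE, 3 pairs), or 34.2-fold (adjusted p = 1.32e-05), and its rises in the inhibitor series, sh-control and sh-TOP2B pairs were 5.33, 5.08 and 4.88. GREB1, a hormone-responsive growth regulator, and the sialyltransferase gene ST6GALNAC1, both dim with vehicle in the inhibitor series, rose by at least 2.19 and 2.76, and the transcription factor gene ZBTB16 rose 5.66-fold. TMPRSS2, a membrane protease gene, rose by 2.16 ± 0.19 (adjusted p = 0.0123) and FKBP5, a co-chaperone of steroid receptors, by 1.71 ± 0.20 (adjusted p = 0.0322). The 3 genes that fell past the test were PGM2L1 (-1.29), TMEM158 (-1.11) and the ion cotransporter gene SLC12A2 (-0.46). OPRK1 (-2.32) and AMIGO2 (at least 2.02 lower, dim with DHT in both shRNA pairs) had larger negative values and did not pass. TOP2B (0.09) and TOP2A, dim on both arrays of the inhibitor pair, did not pass either.

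Of 43 measured genes on the list of androgen-induced genes, 15 rose and 0 fell in the test over all genes, and 39 were higher and 1 lower when adjusted over the list alone. The list's median was 1.16 (random lists -0.08 to 0.04), with a camera adjusted p = 6.12e-94, and adjusted p = 4.07e-05 with an estimated correlation. STEAP4 (at least 3.51) and SNAI2 (at least 3.11, chosen after its value was seen), both members and dim with vehicle, varied between pairs and did not pass. Of the other lists, androgen-repressed genes (median -0.68), DNA replication (0.37, with CDC6 at least 0.98 higher and MCM10, dim on 1 vehicle and 1 DHT array, given no size), mitosis (0.23, MKI67 at least 0.53 higher), sterol and fatty acid synthesis (0.16), the unfolded protein response (0.17, DNAJB9 0.56), p53 targets (-0.16, CDKN1A -0.69) and the interferon response (-0.21, IRF1 -0.69) passed camera with the preset correlation. None of these 7 calls held with an estimated correlation (adjusted p = 0.249 for mitosis, 0.251 for the androgen-repressed, replication and sterol lists, 0.356 for p53 targets, 0.423 for the unfolded protein response and 0.643 for the interferon list). In the sterol list ACACA, the gene of acetyl-CoA carboxylase, rose by 0.56, while FASN (0.53) and ELOVL5 (0.59) did not pass.

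limma called 53 of 11865 genes for DHT, 50 higher and 3 lower, and 2288 genes had an unadjusted p under 0.05. A mean difference of at least 1 was seen in 102 genes upward and 53 downward, of which 28 and 2 passed the test. The pairs differed in size: 29 genes were higher and 5 lower by at least 1 in the inhibitor series, against 250 and 213 in sh-control cells and 206 and 173 in sh-TOP2B cells. The beta-actin 3' minus 5' difference was lower with DHT than with vehicle in both shRNA pairs (2.67 against 3.09 and 2.38 against 2.69). In the inhibitor series it was 0.46 against 0.47. Leaving out the inhibitor pair gave 2515 calls, 1105 higher and 1410 lower, so the split of 50 to 3 depends on that pair. Leaving out the sh-control pair gave 1 call and leaving out the sh-TOP2B pair 9, and 5 genes were called without the intensity trend, 20 without the filter on dim genes, 35 with the median over probe sets and 10 from the pairs without the knockdown. Across genes, which are not independent replicates, the DHT differences of the sh-control and sh-TOP2B pairs correlated at r = 0.718, and those of the inhibitor and sh-control pairs at 0.339.

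**Figure D1:**
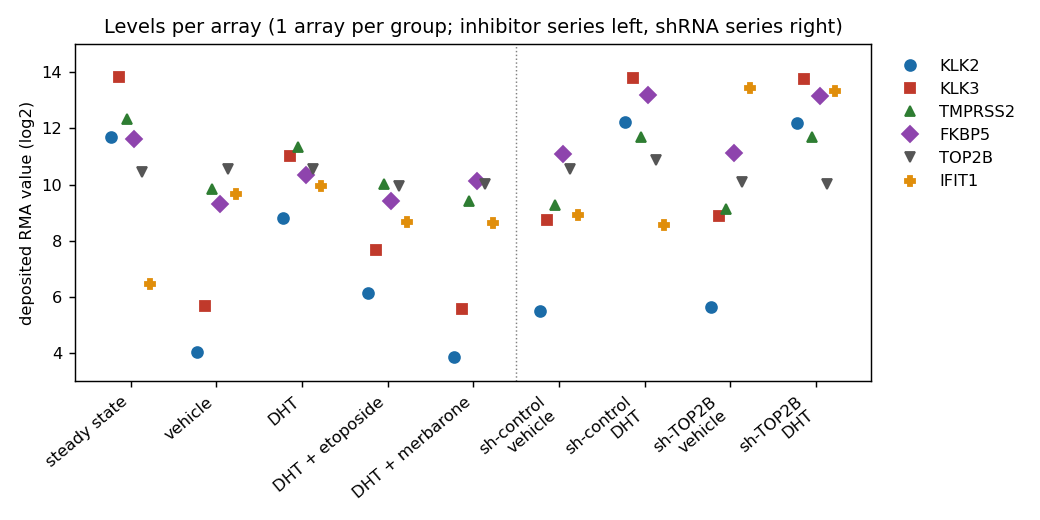
Deposited log2 RMA values (vertical axis) of KLK2, KLK3, TMPRSS2, FKBP5, TOP2B and IFIT1 on each of the 9 arrays (horizontal axis, inhibitor series left of the dotted line). Each point is 1 array. KLK3 stood at 5.68 with vehicle, 11.02 with DHT, 7.68 with etoposide and DHT and 5.56 with merbarone and DHT, and IFIT1 at 8.94 and 8.55 in sh-control cells against 13.43 and 13.32 in sh-TOP2B cells.

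The comparison of etoposide with DHT against DHT alone asks how the transcriptome of androgen-stimulated cells differed when topoisomerase II was poisoned. Genes of the p53 pathway were higher and KLK3 was lower. KLK3 fell by 3.34 ± 0.18, or 10.1-fold (limma adjusted p = 0.00189), from 11.02 to 7.68, between the DHT and the vehicle (5.68) level. The odorant receptor gene OR51E2 fell by 4.06 and LUZP2 by 2.89, while OR51E1 and IL1RAPL1 became dim, falling by at least 3.12 and 2.71. KLK2 was at -2.66 ± 0.62, TMPRSS2 at -1.34 and FKBP5 at -0.93, none of which passed. The median SE over genes was 0.20. As the spread is how far the DHT effects of the pairs differ, genes with an uneven DHT response pass less readily. Not passing is thus no evidence that these genes did not fall. The 3 KLK3 probe sets ranged from -3.34 to -0.01 and the 4 KLK2 probe sets from -2.66 to 0.05. TP53I3 rose by 2.70 and SPATA18 by 2.62, both p53 targets, and the chemokine gene CXCL8 rose by 2.34, TRIM22 by 2.28 and ANKRD20A12P by 2.39.

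Among 32 p53 targets, 10 rose and 0 fell over all genes, 23 were higher adjusted over the list alone, and the median was 0.81 (random lists -0.17 to 0.02). GADD45A, a stress sensor, rose by 2.18, MDM2, which limits p53, by 1.84 and CDKN1A, which encodes the cell-cycle inhibitor p21, by 1.77 (the last pair chosen after their values were seen). The call had a camera adjusted p = 6.45e-47, and adjusted p = 1.17e-08 with an estimated correlation. Of 27 mitosis genes, 5 fell and 0 rose, 17 were lower adjusted over the list alone, and the median was -0.80 (adjusted p = 0.00441 with an estimated correlation). Of these 27 genes 9, DLGAP5 among them, were dim on both arrays; over the 18 others 4 fell, with a median of -0.72 and adjusted p = 0.00455 with an estimated correlation. With dim levels raised to the array median the median over all 27 was -0.26, so its size is uncertain. CCNB1, the cyclin of mitotic entry, fell by 1.68 and KIF2C, dim with etoposide, by at least 0.59. Replication-dependent histone genes had a median of 0.17, with H2BC4 at 0.87 and no member past the test over all genes (3 of 9 higher adjusted over the list alone), and adjusted p = 1.90e-05 with an estimated correlation. The list of 7 topoisomerase genes had a median of -0.40 (adjusted p = 0.0251 with an estimated correlation), with TOP2B at -0.63 without passing. Its only member past the test, TOP2A, was dim on both arrays (4.50 and 2.45), and without it the list did not pass (adjusted p = 0.232, and 0.379 with an estimated correlation).

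Of 27 DNA replication genes, RRM2, a subunit of ribonucleotide reductase, became dim, falling by at least 0.42, and GINS1 fell by 1.12, while PCNA rose by 1.17 and TYMS, the gene of thymidylate synthase, by 2.23 (both chosen after their values were seen). The androgen-induced list had a median of -0.34, with KLK3 and the metalloprotease gene ADAMTS1 (-2.36, chosen after its value was seen) past the test. These 2 lists, together with the androgen-repressed (median -0.64, UGT2B15 -1.45 past the test), immediate early (0.23, KLF4 0.95 and, chosen after its value was seen, MYC -1.31 past the test), luminal identity (-0.20, or -0.12 with arrays centred on control genes), NF-kB (0.24), sterol (-0.26) and unfolded protein response (-0.10, or -0.03 centred, PDIA4 -0.79 past the test) lists, passed camera with the preset correlation. They did not hold with an estimated correlation: adjusted p = 0.607 for replication, 0.428 for androgen-induced, 0.606 for androgen-repressed and unfolded protein response, 0.259 for immediate early, 0.0641 for luminal identity, 0.431 for NF-kB and 0.380 for sterol genes. That correlation comes from the DHT pairs and not from the etoposide array, so failing with it is no evidence against a shift of these lists. Heat shock, integrated stress response and apoptosis effector lists did not pass.

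limma called 124 genes for etoposide, 25 higher and 99 lower, and 74 genes were higher and 168 lower by at least 1. The comparison is of 1 array with 1, and the calls depend on the spread borrowed from the pairs: there were 0 without the intensity trend (1529 genes at an unadjusted p under 0.05), 56 without the filter, 192 with a stricter filter, 0 without the sh-control pair, 29 without the sh-TOP2B pair and 231 against the DHT level fitted from all pairs. Centring the arrays on control genes gave 75 calls and moved the share of higher calls from 20.2% to 30.7%, and quantile normalization again moved it to 31.1%.

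Merbarone with DHT differed from DHT alone in far more genes. KLK3 fell by at least 5.40, or 42.3-fold (limma adjusted p = 0.000103), to 5.56, and KLK2 by at least 3.20 (adjusted p = 0.00212) to 3.86. Both were dim there. KLK3 stood at 5.68 with vehicle, and KLK2 was dim with vehicle too (4.04), so its order between merbarone and vehicle is not determined. TMPRSS2 fell by 1.94, while FKBP5 was at -0.23 (adjusted p = 0.704). Of the glucuronosyltransferase genes, which inactivate androgens, UGT2B15 fell by 5.74, and UGT2B17 and UGT2B28, dim with merbarone, by at least 4.97 and 4.43. BHLHE40 rose by 5.06, GAS2L3, dim with DHT alone, at least 10.6-fold, GADD45B by 4.51, NDRG4 by 4.37 and GADD45A by 4.26. TOP2B fell by 0.54 (limma adjusted p = 0.0499), and TOP2A was dim on both arrays (4.50 and 3.44). The fall of TOP2B with etoposide was larger, with the same SE, and did not pass. The adjustment is more lenient where more genes have low p-values, so passing with merbarone only is no difference between the compounds.

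Of 32 p53 targets, 26 rose and 1 fell (TP53INP1, -0.44, chosen after its value was seen), 28 were higher adjusted over the list alone, and the median was 1.30 (random lists -0.25 to 0.18, adjusted p = 0.000760 with an estimated correlation). PHLDA3 rose by 2.86 and AEN by 2.84. Of 22 genes of the integrated stress response, the programme set off by phosphorylated eIF2 alpha, 14 rose and 0 fell (15 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.00169 with an estimated correlation). DDIT3, which encodes CHOP, rose by 3.95, ATF3 by 3.57 and TRIB3 by 3.26. Of 15 immediate early genes 8 rose and 1 fell, with KLF6 at 4.16 and CCN1 at 3.41 (median 0.97, adjusted p = 0.0213 with an estimated correlation). Of 9 histone genes 8 fell, with H2BC21 at -2.14 and H2BC4 at -1.66 (median -0.83, or -0.54 centred on control genes, adjusted p = 1.11e-07 with an estimated correlation). Of 10 heat shock genes 6 fell and 1 rose, with HSPH1 at -1.35 and DNAJB1 at -0.88 (median -0.47, or -0.18 with arrays centred on control genes, adjusted p = 0.0213 with an estimated correlation). Of 9 luminal identity genes 5 fell, among them SLC45A3 (-3.35) and HOXB13 (-1.53), with a median of -0.59, or -0.30 centred (adjusted p = 0.0113 with an estimated correlation). ACP3, which encodes prostatic acid phosphatase, fell by 1.65, but its probe sets disagreed and their median was 0.16.

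Of 43 androgen-induced genes, 13 fell and 2 rose, with a median of -0.43, or -0.14 with arrays centred on control genes (adjusted p = 0.555 with an estimated correlation). Mitosis genes had a median of -0.59 (-0.31 centred) with 11 of 27 lower (8 of the 17 not dim on both arrays), among them CCNB2 (at least 0.59 lower, dim with merbarone), sterol genes a median of -0.63 (-0.34 centred) with 14 of 24 lower, led by ELOVL6 (-1.16), and NF-kB genes a median of 0.74 (1.03 centred) with 5 of 12 higher, led by CXCL8 (3.34). With dim levels raised to the array median the mitosis median was -0.31, so its size is uncertain. The unfolded protein response list (median -0.38, -0.09 centred, SDF2L1 -1.15) and the androgen-repressed list (median -0.28, but 0.0024 with arrays centred on control genes, ACKR3 -2.05) passed with the preset correlation too. With an estimated correlation these 5 lists gave adjusted p = 0.355 for mitosis, 0.398 for sterol, 0.278 for NF-kB, 0.555 for the unfolded protein response and 0.491 for androgen-repressed genes. The interferon list did not pass.

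limma called 3756 genes for merbarone, 1823 higher and 1933 lower, and 808 were higher and 895 lower by at least 1. The count stayed within 1.5 times under the alternatives, but centring on control genes, whose median was 12.38 with merbarone against 12.67 with DHT, shifted the median of all genes by 0.29 and moved the share of higher calls from 48.5% to 75%. This centring adds one constant to every gene and leaves the control genes themselves at a median of 0.19 (from -0.09), so it over-corrects, and the medians that took the other sign, those of androgen-repressed genes (-0.28 to 0.0024), DNA replication (-0.25 to 0.03) and break repair (-0.08 to 0.20), are no evidence of a change either way. The beta-actin 3' minus 5' difference was 0.46 on the DHT array, 0.54 with etoposide and 0.38 with merbarone.

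Set directly against each other at the same dose and time, the compounds differed in 3866 genes by limma, 1602 higher and 2264 lower with etoposide. KLK3 and KLK2, both dim with merbarone, passed on their deposited differences of 2.12 and 2.29 and were higher with etoposide by at least 2.06 and 0.54. TMPRSS2 (0.60), FKBP5 (-0.71) and TOP2B (-0.09) did not pass. UGT2B15 was higher with etoposide 19.6-fold, and the chemokine gene CCL8, LPAR6, ANKRD36B and UGT2B17, dim with merbarone, by at least 4.11, 4.10, 3.68 and 2.62. GAS2L3 (at least 3.38, dim with etoposide), KLF6 (-4.00), BHLHE40 (-3.95), GADD45B (-3.79) and GBP1 (-3.69) were lower with etoposide. Of 9 histone genes 8 were higher with etoposide (median 0.99, H2BC4 2.53, adjusted p = 2.45e-15 with an estimated correlation), and of 22 integrated stress response genes 16 were lower (median -0.85, TRIB3 -3.36, adjusted p = 0.00537 with an estimated correlation). Heat shock genes had a median of 0.44, or 0.22 with arrays centred on control genes (HSPH1 1.49, adjusted p = 0.0328 with an estimated correlation). The p53 list (median -0.48, GADD45A -2.07) and immediate early list (-0.66) passed with the preset correlation only, with adjusted p = 0.699 and 0.168 with an estimated correlation. Centring on control genes moved the share of genes higher with etoposide from 41.4% to 23.4% of the calls and the median of all genes from -0.03 to -0.24. The luminal list changed from 0.16 to -0.05 and control genes from 0.01 to -0.20 with centring, and topoisomerases from -0.08 to 0.03 with quantile normalization again.

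Of the 25 genes higher with etoposide, 19 were also higher with merbarone (3.84 for independent lists), and of the 99 lower, 63 were also lower (16.1 for independent lists), with 1 and 6 called the opposite way. Both comparisons use the same DHT array, which cannot be split, so part of the excess may come from it. Across genes their differences correlated at 0.325. Simulated arrays with no effect gave 0.50, which a shared reference and equal spread fix in advance. The real differences had unequal spread (SD 0.36 with etoposide and 0.75 with merbarone), so these correlations are not comparable. The covariance was 0.0888, above the 0.0276 simulated for the shared array alone.

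**Figure D2:**
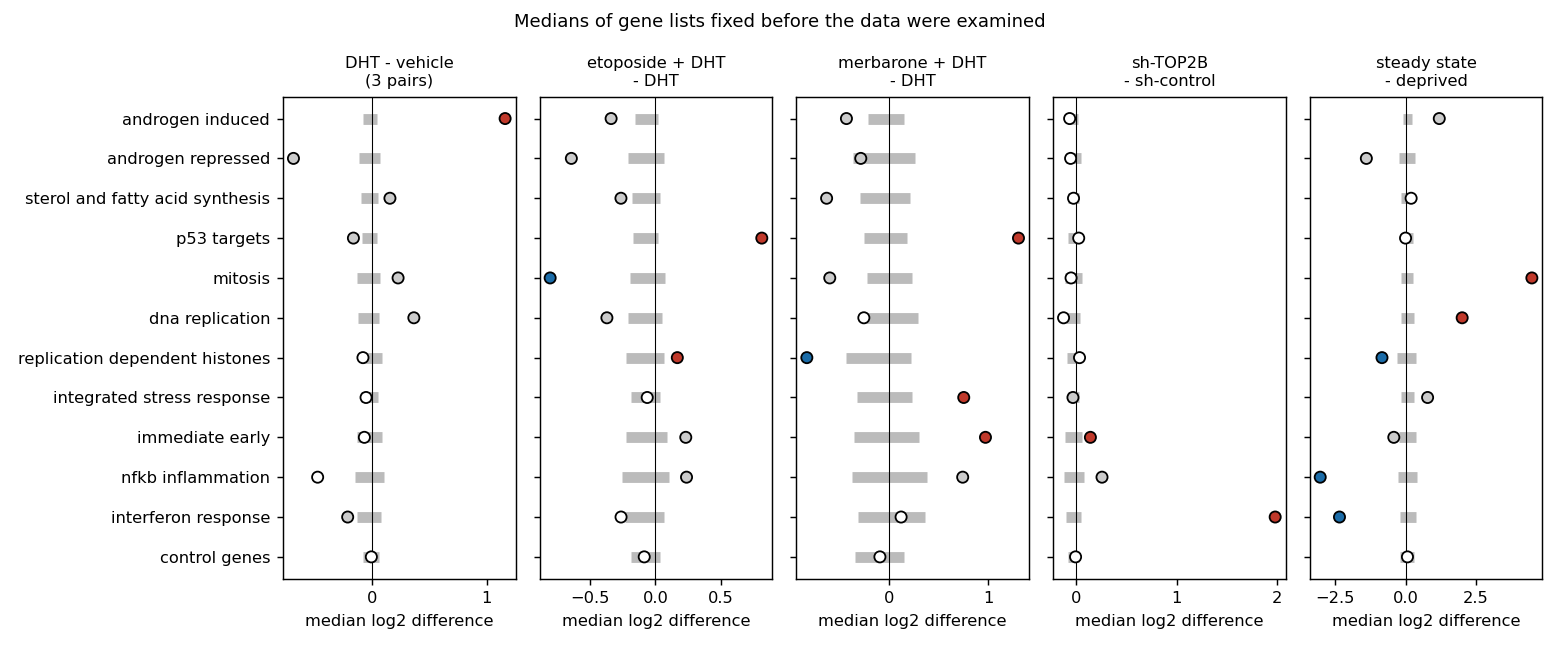
Median log2 difference (horizontal axes) of 12 gene lists in 5 comparisons. Grey bars span the central 95% of medians of 10000 random lists matched on expression, red and blue points passed camera with both the preset and an estimated correlation, grey points with the preset one only, and white points with neither. For the histone list the estimated correlation was 0, so its second test is no stricter than the first. The p53 list stood at 0.81 with etoposide and 1.30 with merbarone, and the interferon list at 1.98 in sh-TOP2B cells.

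Whether the DHT response as a whole was retained under the compounds was measured on 250 genes that were higher by at least 1 in the sh-control pair. Their median response in the inhibitor series was 0.27 with DHT, 0.08 with etoposide and DHT and 0.04 with merbarone and DHT, each against vehicle. Less the median of 14 control genes, these were 0.27, 0.16 and 0.13. Against DHT alone their median was -0.24 with etoposide (random lists -0.10 to 0.00; 171 genes lower, 74 higher) and -0.26 with merbarone (random lists -0.06 to 0.05; 155 lower, 91 higher). With arrays centred on control genes the merbarone median was 0.02, but that of all genes was 0.29 and that of the control genes 0.19, so the chosen genes lay 0.26 below all genes under both scalings (0.18 below with etoposide). For the same genes, one constant added to all genes cannot change this gap. Less the median difference of control genes, a scaling chosen after seeing the data, the medians were -0.15 with etoposide and -0.17 with merbarone. The 213 genes lower by at least 1 in the sh-control pair had medians of -0.07 and -0.03 against DHT alone, both inside the range of random lists (-0.09 to 0 and -0.07 to 0.05).

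**Figure D3:**
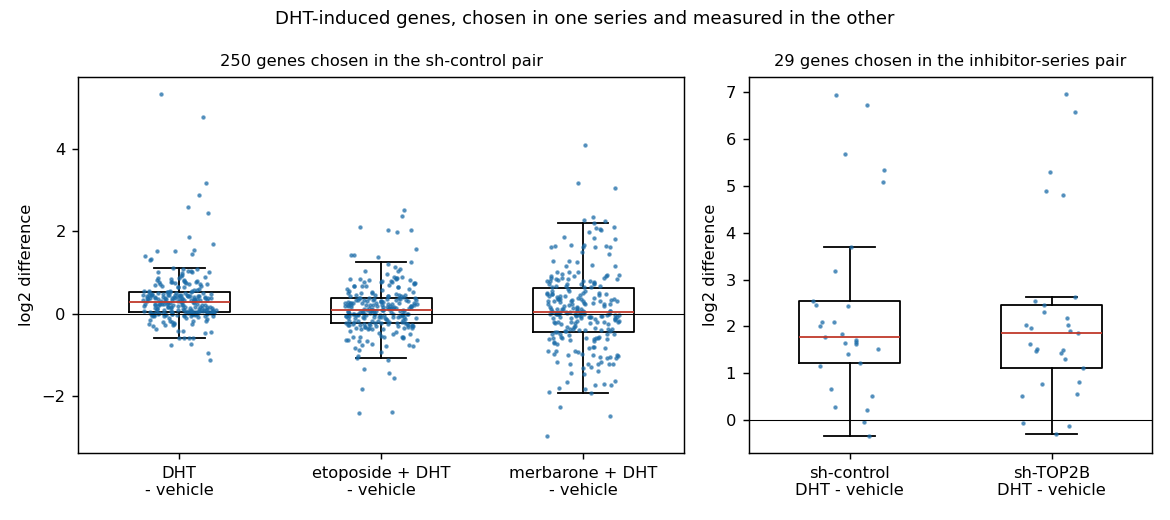
Log2 differences (vertical axis) of DHT-induced genes chosen in one series and measured in the other. Each point is a gene, boxes span the quartiles and red lines mark medians. The medians of 250 genes were 0.27, 0.08 and 0.04 in the inhibitor series, and those of 29 genes 1.77 in sh-control and 1.85 in sh-TOP2B cells.

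The shRNA series asks the same of TOP2B itself. TOP2B stood at 10.54 (vehicle) and 10.87 (DHT) in sh-control cells and at 10.09 and 10.01 in sh-TOP2B cells. It was lower by 0.45 and 0.86, on average -0.66 ± 0.12 (SE, 2 pairs), and did not pass (limma adjusted p = 0.0932). In the inhibitor series TOP2B was at 10.44 in steady state, 10.55 with vehicle, 10.57 with DHT, 9.94 with etoposide and 10.03 with merbarone. In sh-TOP2B cells interferon-induced genes were higher with and without DHT. The antiviral genes OASL and RSAD2 rose by 4.91 and 4.67. The chemokine genes CCL5 and CXCL11 and RGS2, a regulator of G protein signalling, each dim on at least 1 sh-control array, rose by at least 5.82, 5.49 and 5.26. No gene fell past the test; MEIG1 was at least 0.19 lower, dim in sh-TOP2B cells, and did not pass.

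Of 18 interferon response genes, 15 rose and 0 fell, 16 were higher adjusted over the list alone, and the median was 1.98 (random lists -0.10 to 0.05, adjusted p = 2.36e-24 with an estimated correlation). IFIT1 rose by 4.63, IFIT3 by 4.61 and OAS1 by 3.83, while MX1 was at -0.15 and IRF7 at 0.21 (chosen after their values were seen). The medians were 1.96 with vehicle and 2.00 with DHT. The beta-actin 3' minus 5' differences were 3.09 and 2.67 on the sh-control arrays and 2.69 and 2.38 on the sh-TOP2B arrays. Of 15 immediate early genes 2 rose past the test, KLF4 by 2.17 and FOS by no exact size (camera adjusted p = 0.00648 for the list with an estimated correlation). FOS was dim on both sh-control arrays and on 1 sh-TOP2B array, so raising those levels to the median gives no bound. The list's median was 0.14, at -0.0022 with vehicle and 0.23 with DHT. Apoptosis effectors (median 0.13; of 14 only TNFSF10, the gene of TRAIL, rose, by 3.77), integrated stress response (median -0.03, with 9 of 22 members positive and 13 negative, of which ATF3 at 1.02, CEBPB at 0.89 and WARS1 at 0.69 passed) and NF-kB genes (median 0.26, no member past the test) passed with the preset correlation, with adjusted p = 0.0686, 0.708 and 0.328 with an estimated correlation. KLK3 (0.06), TMPRSS2 (-0.08) and FKBP5 (-0.01) did not pass, nor did KLK2, whose direction is not determined, as it was dim on both vehicle arrays, and the median of the androgen-induced list was -0.06. limma called 124 genes, 124 higher and 0 lower, 81 without the intensity trend and 291 without the inhibitor pair (251 higher, 40 lower). With only the 4 shRNA arrays 315 were called, 257 higher and 58 lower. The labels name a single sh-TOP2B vector, with no second hairpin or rescue among the arrays.

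The DHT response differed between sh-TOP2B and sh-control cells in 0 genes by limma, with 147 genes at an unadjusted p under 0.05 and 89 genes differing by at least 1 in each direction. The largest differences in the deposited values were those of SCNN1G, LKAAEAR1, RHD, PGC and PRR7 upward and EMP1, CXCL11, CXCR4, FA2H and ANKS1B downward, none of which passed. Only PGC (2.05, from responses of 1.03 in sh-control and 3.08 in sh-TOP2B cells) and CXCR4 (-1.89) were not dim on any of the 4 arrays, and the sizes of the other 8 are uncertain. KLK3 rose by 5.08 in sh-control and 4.88 in sh-TOP2B cells, a difference of -0.20 ± 0.28, and TMPRSS2 and FKBP5 differed by 0.11 ± 0.43 and -0.07 ± 0.48. KLK2 was dim on both vehicle arrays, and its difference has no exact size. Over the 29 genes higher by at least 1 with DHT in the inhibitor series, the median response was 1.77 in sh-control and 1.85 in sh-TOP2B cells. The median difference in response per gene was -0.05 (19 lower, 10 higher), inside the range of random lists (-0.10 to 0.12). In level with DHT, not in response, 26 of these 29 genes were lower in sh-TOP2B than in sh-control cells (median -0.07, random lists -0.11 to 0.07). Camera on the responses of these n = 29 genes gave p = 0.0534, and p = 0.190 with an estimated correlation. The androgen-induced list had a median difference of -0.12 with 32 of 43 genes lower, below random lists (-0.07 to 0.07), and adjusted p = 0.315 by camera. This fit has 1 residual degree of freedom and recovered 25% of simulated differences of log2 2, so most differences of that size would be missed. Its spread is how far the inhibitor-series and sh-control DHT effects differ, and these differed in size (29 against 250 genes higher by at least 1). The simulation gave DHT-responsive genes no larger spread, so its recovery may not hold for them.

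Cells in steady state were compared with androgen-deprived cells as the baseline of the inhibitor series. The beta-actin 3' minus 5' difference was 0.70 in steady state and 0.47 with vehicle. KLK3 was higher in steady state by 8.13 ± 0.18 (limma adjusted p = 8.29e-06), TMPRSS2 by 2.48, FKBP5 by 2.31 and KLK2, dim with vehicle, by at least 6.03. Cell-division genes were higher too: all 27 tested mitosis genes rose, with a median of 4.49, or 4.21 with dim levels raised to the array median (NEK2 at least 5.00, ANLN at least 4.89 and KIF20A at least 4.84), as did 23 of 27 replication genes (RRM2 5.40). TOP2A (10.42 against 4.42), PEG3 and the mitotic kinase gene PBK, all dim with vehicle, rose by at least 4.76, 6.62 and 5.92. Inflammatory genes were lower: 11 of 12 NF-kB genes fell (median -3.04, or -2.67 with dim levels raised), and 15 of 18 interferon genes fell. The chemokine gene CCL20 and IFIT3 were dim in steady state and fell by at least 7.55 and 4.11, PTGS2, which encodes cyclooxygenase 2, at least 51.8-fold, and FEZ1, KRT20 and LCN2 by at least 6.68, 6.38 and 7.30, all dim there too. The mitosis, replication, NF-kB, interferon, histone (8 of 9 lower, H2BC4 -1.73) and break repair (9 of 19 higher, BRCA1 3.30) lists held with an estimated correlation (adjusted p = 5.86e-18, 0.00834, 1.81e-06, 0.00776, 5.65e-09 and 0.000204). Androgen-induced genes (median 1.20, 21 of 43 higher, 1 lower), androgen-repressed genes (-1.40, 9 of 14 lower, 1 higher), immediate early genes (-0.42, EGR1 at least 3.94 lower, dim in steady state), integrated stress response genes (0.78, CHAC1 1.44) and topoisomerases (0.40) passed with the preset correlation only, with adjusted p = 0.269, 0.619, 0.113, 0.148 and 0.0589 with an estimated correlation. For the histone and break repair lists the estimated correlation was 0, so holding with it is no further support. The histone median was -0.84 while those of mitosis and replication were 4.49 and 2.01, so the histone values did not follow cell division. Of 4 tested markers of other cell types 1 was lower, and neither the 3 neuroendocrine genes nor the 14 control genes passed as lists. limma called 3336 genes, 1859 higher and 1477 lower, and centring on control genes moved the share of higher calls from 55.7% to 41.2%, the median of all genes from 0.04 to -0.08 and that of neuroendocrine genes from 0.10 to -0.02.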

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

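The tests of explanations in this part were chosen after the results were seen.

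Between sh-TOP2B and sh-control cells, the DHT response of p53 targets differed by a median of 0.11 (-0.13 against -0.32) with a camera adjusted p = 0.0438, and adjusted p = 0.988 with an estimated correlation. PEG3 was at -1.46 and -1.65 with DHT in sh-control and sh-TOP2B cells; its value of 0.17 in the inhibitor series lies between 2 levels below the array medians (5.47 and 5.64) and decides nothing, and the difference was not tested. IFITM1 was at 0.15 in the inhibitor series and at -0.84 and -0.67 in the shRNA pairs, also untested.

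DHT-induced genes were lower under etoposide and merbarone in the deposited values. Genes that happened to be high on the DHT array would fall back by chance, but genes chosen on other arrays had medians of -0.24 and -0.26, below random lists, and the higher of both percentiles among random lists was 0, which argues against a fall of all genes alike. Centring on control genes moves all genes by one constant, so the chosen genes stay 0.18 and 0.26 below all genes by construction, which is no further evidence. Less the median difference of control genes their medians were -0.15 and -0.17. A secondary effect of the stress that the compounds set off stays open, since p53 targets rose under etoposide (median 0.81) and the design has no inhibitor array without DHT. Reduced topoisomerase II activity at androgen-responsive genes may equally account for the fall, and these explanations cannot be told apart here.

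Interferon genes were higher in sh-TOP2B cells. RNA quality is argued against, though the arrays compared also differ in DHT: on the sh-TOP2B vehicle and sh-control DHT arrays, with nearly equal beta-actin 3' minus 5' differences (2.69 and 2.67), the list still differed by a median of 2.10. An effect of this hairpin or its transfection apart from TOP2B, such as a response to double-stranded RNA, could give the median of 1.98 and cannot be told apart from an effect of TOP2B without a second hairpin. Under etoposide the list's median was -0.26, below random lists (-0.23 to 0.07), with 13 of 18 members negative and 5 positive, so no rise of the list was seen on that array. Under merbarone the median was 0.12, with 10 members positive and 8 negative, and a median near 0 over members that go both ways decides nothing. With 1 array each at 1 time, whether a block of topoisomerase II raises interferon genes stays open.

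No difference in the DHT response of single genes was shown in sh-TOP2B cells. Of the 29 chosen genes 19 had a lower and 10 a higher response there (median -0.05, random lists -0.10 to 0.12). The level with DHT, which is not a response, was lower in 26 (median -0.07, random lists -0.11 to 0.07). The response of the androgen-induced list differed by -0.12 (random lists -0.07 to 0.07), and the fit recovers only 25% of simulated log2 2 differences. Whether the response was fully retained thus stays open. TOP2B differed by only -0.66 on the log2 scale, so an effect of a deeper loss cannot be told apart from no effect. Bright probe sets near saturation could hide a weaker response. Over the 16 chosen genes below 11 on the sh-control DHT array the median difference was -0.0461, with 11 lower and quartiles of -0.37 and 0.02. That array is also subtracted in the difference, so choosing low levels on it pushes the difference upward. Saturation therefore stays open.

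For the DHT effect, the real split of the 6 paired arrays called 47 genes. The 3 other splits that part all 3 pairs called 0. The 6 remaining ones part a single pair, so that they rest on that pair alone and could hardly call genes, and called 0 too. Thus 1 split gave as many, and with 10 splits in all, a share under 0.05 is not possible.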

How the results depend on the processing

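The comparisons with the fitted level, the shift by the median difference of control genes and the lists without dim members were chosen after seeing the data, and all other alternatives before. Calls for the DHT effect (53) numbered 20 without the filter on dim genes, 35 with the median over probe sets, 5 without the intensity trend, 10 from the 2 pairs without the knockdown and between 1 and 2515 in the leave-one-out fits. Knockdown calls (124) numbered 81 without the trend, 291 without the inhibitor pair and 315 with only the 4 shRNA arrays. Etoposide calls (124) numbered 56 without the filter, 192 with a stricter one, 0 without the trend, 75 centred on control genes, 0 to 29 in the leave-one-out fits and 231 against the fitted level. Counts for merbarone, for etoposide against merbarone and for steady state stayed within 1.5 times, and the difference between DHT responses stayed at 0 under each alternative; with a pair left out that fit has no residual degrees of freedom. A fit without the inhibitor pair could not be made for either compound against DHT or for steady state, whose reference array is in that pair. Taking log2 of linear values was not needed, as the values already were log2. The median of DHT-induced genes under etoposide (-0.24) was -0.12 with genes chosen at 0.5, and under merbarone (-0.26) it was -0.13 at 0.5, -0.43 over the androgen-induced list and 0.0249 centred on control genes; less the median difference of control genes they were -0.154 and -0.170. The median difference between DHT responses (-0.05) was -0.12 over the androgen-induced list, -0.0935 centred and -0.0807 less that of control genes. Without members below the array median on all arrays compared, the topoisomerase list lost its call under etoposide (-0.38). Of 2541 recomputed values of named genes, 2307 kept direction and side of the threshold, 180 lost the call, 44 gained it and 10 changed sign. With the median over probe sets these were TOP2A for DHT (-0.37), BCL2 (-0.0187), TOP2A (0.0104) and KLK2 (-0.0441) for the knockdown, TNFRSF10C between DHT responses (-0.0490), and ACP3 (0.16) and TOP2A (0.33) for merbarone. TOP2B for DHT was -0.0251 without the sh-control pair and 0.177 without the sh-TOP2B pair, FKBP5 for merbarone 0.0596 centred on control genes, and TOP2B between the compounds 0.0338 after quantile normalization again. The cause was not tested. Centring moved the higher share of calls from 48.5% to 75% for merbarone, 41.4% to 23.4% between the compounds, 55.7% to 41.2% for steady state and 20.2% to 30.7% for etoposide.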

Other observations

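The tests of median gene span below were planned before their result was seen, though after the names of the leading etoposide genes were known, and the count among the largest falls was chosen after. The genes in the next paragraphs were chosen after their values were seen.

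Levels of 3 genes on the androgen-deprived arrays of the 2 series are given without a test. CCL20 stood at 13.18 in the inhibitor series with vehicle and at 10.85 in sh-control cells with vehicle, against 4.19 in steady state, and DHT left it at 13.09 in the inhibitor series and 9.69 in sh-control cells. TOP2A stood at 4.42 with vehicle in the inhibitor series, 8.97 in sh-control cells and 10.42 in steady state, and PTGS2 at 11.32, 6.68 and 2.86. The lowest level of each of these genes lies below its array's median and has no exact size. The series also differ in sorting, transfection and the beta-actin 3' minus 5' difference, so these levels are side by side only.

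Both compounds raised TYMS (2.23 with etoposide, 1.71 with merbarone) and lowered RRM2, dim with either (at least 0.42 and 0.48), 2 genes of nucleotide supply that usually move with the cell cycle. The odorant receptor gene OR51E2, at 11.26 with DHT, fell to 7.21 with etoposide and 6.69 with merbarone. Under merbarone the interferon list parted: IRF1 rose by 3.50, IFIH1 by 1.94 and HERC5 by 1.80, while OAS1 fell by 1.37 and IFIT1 by 1.34. In sh-TOP2B cells, genes outside the interferon list rose too, among them the secreted factor genes MSMB (3.70) and TFF1 (3.56) and the complement gene C3 (at least 2.01, with sh-control levels below the array median).

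A hypothesis is that topoisomerase II helps to transcribe long genes, so that genes spanning at least 100 kb would be lower under the compounds. With etoposide their median minus that of shorter genes was -0.0761, outside random lists (-0.02 to 0.01). Long genes were thus slightly lower in general, by less than the 0.1 set in advance. With merbarone the difference was 0 (both medians exactly 0, random lists -0.015 to 0.009) and with the knockdown 0.00149 (random lists -0.008 to 0.008). No general shift was seen in either. Among the 168 genes lower by at least 1 with etoposide, 67 spanned at least 100 kb (random lists 20 to 39), such as IL1RAPL1 (1369 kb), GRIK2 (676 kb) and LUZP2 (586 kb). Among the 74 genes higher by at least 1 with etoposide, 7 were long (random lists 7 to 19). With merbarone 179 of 895 lower and 158 of 808 higher genes were long (random lists 138 to 180 and 124 to 165). Both merbarone counts lie inside the range but near its upper limit, so a small excess there is neither shown nor excluded. Without any inhibitor, the median of long genes in steady state minus that of shorter genes was -0.13 (random lists -0.03 to 0.03), with beta-actin 3' minus 5' differences of 0.70 in steady state and 0.47 with vehicle. Long genes were 235 of 800 lower in steady state (random lists 119 to 158) and 103 of 765 higher (random lists 117 to 156). Over the 3 DHT pairs they were 24 of 53 lower and 36 of 102 higher (random lists 4 to 15 and 11 to 25), but in the inhibitor-series DHT pair 1 of 5 lower and 7 of 29 higher (random lists 0 to 2 and 1 to 9). The excess under etoposide thus lies among the falls alone, yet falls without an inhibitor can show it too, and what accounts for it stays open.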
